A study of Xenopus tropicalis with 9 samples.

How the data were processed

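RNA was measured by sequencing in 9 libraries from adult Xenopus tropicalis: head and heart of a female and of a male, lung, ovary, intestine and GI tract of a female, and testes of a male. Per the labels' protocols, total RNA was isolated with Qiagen kits and libraries were made with Kapa mRNA reagents for Illumina sequencing. The labels give 1 tissue, sex and age class for each library. Nothing in the labels says whether the samples came from separate animals, so p-values measure the spread between these samples.

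The authors deposited 1 table of counts per gene and 1 table of TPM (transcripts per 1000000), each with a column per library. RSEM 1.3 and deepTools are named in the submitters' processing notes, with no role for either. The deposited counts are read here as RSEM expected counts rounded to whole numbers, because 1272 cells have a count of 0 and a TPM above 0. They were not scaled for depth, and their totals differ between libraries. The deposited TPM values, made by the authors, sum to 1000000 in each library and have 2 decimals. The aligner, the genome build and the gene annotation are not given in the sources used here, so no coordinates are given.

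Both tables hold 30331 rows, of which 1 collects reads without a gene name and was left out of the tests. Of the other 30330, 15165 carry a gene symbol and 15165 only a code. The RefSeq gene table of assembly UCB_Xtro_10.0 was used for names only and matched 14552 of the symbols. Genes that share reads with near-identical copies, such as tandem duplicates, histone and globin genes, have uncertain levels where the counting could split their reads. No library column was left unused.

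The depth ranged from 27628254 to 35044545 counts per library. A floor of 3 counts corresponds to 0.086 to 0.109 CPM (counts per 1000000). Shares of counts are given with 95% Wilson intervals, which cover counting error only, as does the floor.

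Libraries were grouped by the tissue and sex labels. Replicate numbers follow the order in which samples are listed and pair nothing, so sex was the block used. Head against heart was tested with the quasi-likelihood F test of edgeR 4.0.16 on the 4 head and heart libraries, with a term for tissue, TMM scaling factors and edgeR's default filter on low counts, which left 19276 genes. Female against male was tested in the same libraries with terms for tissue and sex, which leaves 1 residual degree of freedom. That degree of freedom is the tissue by sex interaction. These p-values therefore set the sex effect against its disagreement between head and heart, and not against the spread between animals of a sex. Ovary against testes, intestine against GI tract, and each tissue against the mean of the other 6 were tested in a single fit of all 9 libraries with a mean per tissue (23090 genes). In that fit the spread comes from the head and heart pairs, and a tissue with 1 library is assumed to vary like them. The threshold was a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken from the F statistic. A gene was called tissue-enriched, with no test, when its mean TPM was at least 10 in 1 tissue and at least 4 times that of every other tissue. Spearman correlations of log2(TPM + 1) described how alike the libraries were.

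For this study 27 gene lists were fixed, and 596 of their 678 symbols were found in the tables. They cover cardiac muscle, skeletal muscle, neurons, glia, photoreceptors and retina, lens, pituitary, epidermis, cartilage and bone, intestinal epithelium, stomach, exocrine pancreas, liver, lung epithelium, motile cilia, oocytes, meiosis and piRNA, spermatids and sperm, gonadal soma and sex steroids, cell cycle, smooth muscle, erythrocytes, immune cells, endothelium, mitochondrial oxidation, glycolysis, and stress and immediate early genes. Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and with fry and an estimated correlation as alternatives. With an estimated correlation, camera also bases its test on the few residual degrees of freedom of the fit. Calls can then be lost even where the members of a list are not correlated. Counts of called members are given with p-values adjusted over all genes tested and adjusted over the list alone. For pairs of single libraries, the median TPM ratio of a list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Random members were drawn independently, so a list whose members vary together reaches an extreme percentile more easily. The percentiles are descriptive.

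The genes named are, by rule, the 10 with the largest fold change per direction among called genes with a symbol (at least 20 TPM in the higher tissue for tissue comparisons), the 5 most abundant called and enriched genes per tissue, and the most abundant members of each list. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Where the planned test called no gene, named genes were taken from the fit with sex as a block or, for single libraries, from the 12 largest TPM ratios per direction under the size rule, and the text says so.

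The alternatives were DESeq2's size factors in edgeR, the Wald test of DESeq2 1.42.0, limma on log2(TPM + 1), no low-count filter, a filter of at least 50 counts in 2 libraries, leaving out the 20 most abundant genes of each library, leaving out each head and heart library, sex as a block, size rules, and other correlations and thresholds. Further alternatives were chosen after seeing the data. They left out genes high in ovary, in ovary or lung, or at most 0.5 times as high in testes as in GI tract, left out the female heart, female lung and male testes libraries together, or used sex as a block in DESeq2 and camera.

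The fits were tested on simulated data drawn from the real means and library sizes, with 200 changed genes. With a biological coefficient of variation (BCV, the relative spread between samples) of 0.2, edgeR recovered 100 of 100 genes at 4-fold in head against heart, 87 in ovary against testes and 88 in intestine against GI tract. With a BCV of 0.7 it recovered 0 of 100 genes at 16-fold in each of these 3 comparisons, 3 in female against male, 50 in head against the other tissues and 35 in lung against the others. The BCV of the real libraries was 0.761 in the fit with tissue and 0.675 with tissue and sex. Camera, run only at a BCV of 0.2, called the raised list in 6 of 6 simulated comparisons and the unchanged list in 0. The genes were simulated independently, so this cannot test the preset correlation on lists with correlated members. In the real head and heart libraries the estimated correlation ran from -0.0499 (epidermis) to 0.973 (oocyte).

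R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.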

Results

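Transcript levels were measured by mRNA sequencing in 9 libraries from 7 adult tissues of the western clawed frog, Xenopus tropicalis. Head and heart were each sampled from a female and from a male (n = 2 per tissue). Lung, ovary, intestine and GI tract came from females and testes from a male, with 1 library each and therefore no replicate check. Total counts were 31583846 in female head, 30045813 in male head, 33530721 in female heart, 34202200 in male heart, 30105334 in female lung, 27628254 in ovary, 30693932 in testes, 32671439 in intestine and 35044545 in GI tract. Genes with at least 1 TPM numbered 17791 in testes, 17744 in female head and 17673 in male head, against 12938 in female heart, 12497 in male heart and 9629 in ovary. The 13 mitochondrially encoded protein genes took 11.01% of the counts in male heart (95% Wilson interval 11.004 to 11.02) and 5.83% in female heart (5.82 to 5.84), and 0.0649% in ovary (0.0640 to 0.0659).

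The head libraries and the gut libraries were each nearest to one another, and the hearts were not. Spearman's rho across 28261 genes was 0.931 between the head libraries and 0.923 between intestine and GI tract. Both hearts correlated more closely with female lung (0.926 for female and 0.836 for male heart) than with each other (0.824). Testes was nearest to GI tract (0.823) and ovary to female heart (0.781), and ovary and testes correlated at 0.694. These are correlations across genes, which are not independent replicates. Counts of the head pair, the heart pair, the gut pair and the female heart and lung pair differed by more than sampling noise, with a chi-square per degree of freedom of 109 for the heads and 1076 for the hearts, so all libraries were kept as separate samples.

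**Figure D1:**
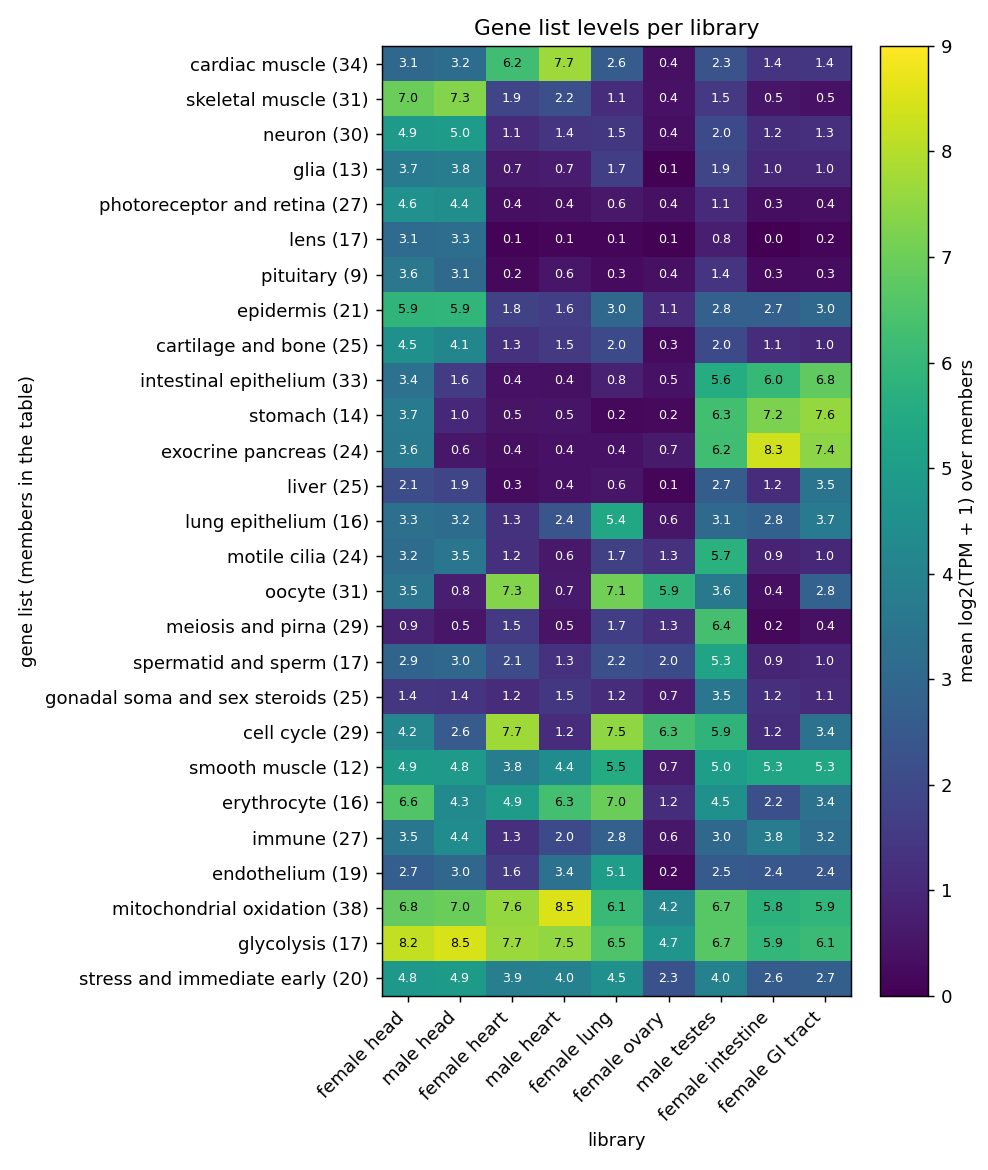
Mean log2(TPM + 1) over the members of each of the 27 gene lists (y axis, number of members in brackets) in each of the 9 libraries (x axis), as a colour scale from 0 to 9 with the value printed in each cell. Skeletal muscle, neuron, eye and epidermis lists were highest in the head libraries, and the oocyte list was high in female heart and female lung as well as in ovary.

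The first question was which genes set head and heart apart. The heart libraries held high levels of contractile genes of heart muscle. The light chain genes myl3 and myl7 reached 26780 ± 2797 and 23980 ± 5925 TPM in heart (mean ± SD, n = 2) against 115 ± 3.54 and 1.57 ± 1.82 in head, and the atrial natriuretic peptide gene nppa reached 2211 ± 619 against 0.225 ± 0.219. The head libraries held transcripts of muscle, skin, brain, eye and gland. They included the fast troponin C gene tnnc2 (5921 ± 1511 against 0.885 ± 0.530), the basal keratin gene krt5.4 (6290 ± 72.6 against 1.14 ± 1.19), the rod opsin gene rho (1250 ± 255 against 0.235 ± 0.332) and the synaptic fusion gene snap25 (486 ± 24.8 against 6.85 ± 6.42).

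In the planned test without a sex term, edgeR called 0 of 19276 genes between head and heart, although 4670 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0664. DESeq2 called 3907 genes (3254 higher in head, 653 in heart) and limma on log2(TPM + 1) called 3912 (3838 and 74). With sex as a block, edgeR called 2784 genes, 2510 higher in head and 274 in heart. The fit with the block leaves 1 residual degree of freedom, so its p-values lean on spread shared across genes. The 4 libraries did not weigh equally: edgeR without the block called 6091 genes without the female heart, 10396 without the male heart, 559 without the female head and 458 without the male head. Of the 2784 genes called with the block, 2439 were also called, in the same direction, when the female heart was left out. Named genes below come from the fit with the block, by the fixed rule.

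Genes called higher in head with the largest folds were those at or near 0 in both hearts, so their levels are given instead of a fold. The rod opsin gene rho stood at 1430 TPM in female head and 1069 in male head against 0.47 and 0 in the hearts. edgeR gave it an adjusted p of 8.55e-11 with the block and 0.073 without it. The homeobox gene dlx5, which acts in craniofacial development, stood at 66.0 and 78.1 TPM in the heads and 0 in both hearts. The muscle acetylcholine receptor subunit gene chrnd (40.42 and 31.5) and the skeletal muscle calcium channel subunit gene cacng1 (32.9 and 39.3) were likewise at 0 in both hearts. The other genes named by the rule were ly6g6d, degs3, fut6, agr3, xa-1 and cuzd1.2, of which ly6g6d was the most abundant, at 1809 and 1388 TPM in the heads.

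Of the genes called higher in heart, myl7 had the largest log2 fold change, -15.35 for head minus heart (SE 2.11, edgeR with the block). Its edgeR adjusted p was 1.39e-10 with the block and 0.0664 without it. After myl7 came the slow myosin heavy chain gene myh15 (-14.73, SE 2.12) and the hormone gene nppa (-14.46, SE 1.82). The cardiac troponin I gene tnni3 (-12.74, SE 1.86) and the cardiac troponin T gene tnnt2 (-11.52, SE 1.71) were next. The cardiac transcription factor gene nkx2-5 stood at 10.8 and 47.8 TPM in female and male heart and at 0 and 0.05 in the heads. The others were the natriuretic peptide gene nppb, the membrane protein gene popdc2, the light chain gene myl3 and lrrc10.

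Members of the cardiac list separated the tissues in both fits. With the block, 26 of its 34 tested members were called higher in heart and 3 higher in head. Without it, 27 were lower and 4 higher in head when adjusted over the list alone, and camera called the list lower in head (adjusted p = 2.94e-14). With an estimated correlation that adjusted p was 0.483. The skeletal muscle list was called higher in head for 23 of 29 members with the block, and for 23, with 1 lower, when adjusted over the list alone (camera adjusted p = 3.44e-10, or adjusted p = 0.286 with an estimated correlation). Its most abundant members did not separate the tissues. The skeletal actin gene acta1 stood at 29530 ± 11170 TPM in head and 34230 ± 4767 in heart, and the muscle creatine kinase gene ckm at 24170 ± 1608 and 14690 ± 3339.

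Neural and sensory lists were higher in head. With the block, edgeR called 25 of 29 neuron genes, 9 of 13 glia genes, 24 of 27 photoreceptor and retina genes, 12 of 13 lens genes and 6 of 6 pituitary genes higher in head and none lower. When adjusted over the list alone in the fit without the block, these counts were 24, 6, 24, 13 and 6. Examples are the growth cone gene gap43 (222 ± 17.03 TPM in head against 5.88 ± 3.58 in heart), the myelin protein gene mpz (174 ± 51.7 against 2.40 ± 1.959), the lens crystallin gene crybb2 (1569 ± 372 against 0.5 ± 0.467) and the pituitary hormone precursor gene pomc (551 ± 27.3 against 0.135 ± 0.191). Camera called all 5 lists, with adjusted p of 4.98e-10, 2.19e-04, 3.03e-12, 6.05e-09 and 9.52e-05 in that order. With an estimated correlation the adjusted p was 0.286 for the neuron, glia and pituitary lists and 0.237 for the photoreceptor and lens lists.

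Surface and skeletal lists followed the same direction. The epidermis list had 13 of 19 and the cartilage and bone list 13 of 22 members called higher in head with the block, and 15 each when adjusted over the list alone without it. The desmosome gene dsp stood at 274 ± 18.8 TPM in head and 4.34 ± 2.53 in heart, and the bone matrix gene bglap at 793 ± 231 and 0.215 ± 0.149. The most abundant collagen genes, col1a1 (1489 ± 317 against 267 ± 82.7) and col1a2 (1130 ± 249 against 265 ± 142), did not pass. Camera gave adjusted p of 1.06e-07 and 1.65e-07, and adjusted p = 0.237 and 0.286 with an estimated correlation. The motile cilia list was also called (9 of 24 members higher with the block and 9 over the list alone without it, camera adjusted p = 9.62e-06, or adjusted p = 0.462 with an estimated correlation). Digestive lists gave smaller counts with the block: 9 of 22 intestinal epithelium, 3 of 6 stomach, 3 of 10 exocrine pancreas and 7 of 13 liver genes were higher in head. The female head stood apart: the mean log2(TPM + 1) of the exocrine pancreas list was 3.63 there, 0.60 in male head and 0.37 and 0.43 in female and male heart, and that of the stomach list 3.73, 1.05, 0.49 and 0.50. When adjusted over the list alone without the block the counts were 6, 1 and 0, and for liver 9 higher and 1 lower.

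All 38 tested genes of mitochondrial oxidation had a negative fold change for head against heart, with a median log2 of -2.06 (camera adjusted p = 2.94e-14, or adjusted p = 0.483 with an estimated correlation). The ATP synthase subunit gene atp5f1b stood at 820 ± 26.2 TPM in head and 3861 ± 961 in heart. No member passed without the block. With it 2 passed over all genes, 1 of them the muscle cytochrome oxidase subunit gene cox6a2, and 0 over the list alone. On the TPM scale 2 of the 38 members were higher in head. For genes above 10 TPM the median TMM fold change lay below the TPM ratio, by -0.90 log2, and the median over all genes was -0.10 with TMM and -0.17 with DESeq2's size factors. Glycolysis genes went both ways: with the block 3 of 17 were called higher and 2 lower, and without it 3 and 2 over the list alone and 0 over all genes. The lactate dehydrogenase gene ldhb, at 757 ± 79.1 and 4898 ± 484 TPM, was lower in head, and the phosphoglycerate mutase gene pgam2, at 552 ± 195 and 31.6 ± 11.7, was higher.

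The oocyte and cell cycle lists were highest in the female heart and next in the female head, above both male libraries. The mean log2(TPM + 1) of the cell cycle list was 7.72 in female heart, 4.18 in female head, 2.58 in male head and 1.16 in male heart. All 30 tested oocyte genes had a negative fold change for head against heart, which the female heart carried: the mean log2(TPM + 1) of the list was 0.77 in male head and 0.66 in male heart. The list median of log2(TPM + 1) was 6.83 in female heart, 0.202 in male heart, 3.04 in female head and 0.138 in male head. With the block 16 oocyte genes and 4 of 29 cell cycle genes were called lower in head, and 0 of each were called over the list alone without it. Camera without the block called both lists (adjusted p = 0.0013 and 0.021), and the adjusted p was 0.741 for each with an estimated correlation. Of the immune list, 7 of 26 members were higher with the block and 0 over the list alone without it (camera adjusted p = 3.79e-04, or adjusted p = 0.705 with an estimated correlation). The peroxidase gene mpo stood at 111 ± 67.0 TPM in head and 2.09 ± 1.56 in heart.

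The remaining lists held few calls with the block. They numbered 4 higher and 2 lower in head of 14 lung epithelium genes, 2 lower of 21 meiosis and piRNA genes, 3 higher and 1 lower of 16 spermatid and sperm genes, and 2 higher and 2 lower of 22 gonadal soma and sex steroid genes. Without the block and over the list alone, the counts were 5 higher and 2 lower for lung epithelium, 1 higher for sperm and 0 for the others. With the block, smooth muscle gave 1 higher and 2 lower of 11, erythrocytes 1 lower of 15, endothelium 0 of 19, and stress and immediate early genes 1 higher and 1 lower of 19. Median and mean fold changes differed in sign for smooth muscle (-0.13 and 0.44). The intestinal epithelium, liver and erythrocyte lists were called by camera without the block (adjusted p = 5.07e-04, 0.00137 and 0.0288, or adjusted p = 0.483, 0.483 and 0.741 with an estimated correlation). Camera called 17 of the 27 lists without the block and 19 with it, fry called 11 without the block and 5 with it, and 0 were called with an estimated correlation.

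The second question was which genes differ between female and male in both head and heart. Transcripts typical of oocytes were higher in the female libraries of both tissues. The egg coat gene zp4 stood at 56.5 TPM in female head against 0.10 in male head, and at 1366 against 0.53 in the hearts. Its log2 fold change was 10.18 (SE 1.54, adjusted p = 5.48e-08, edgeR, 1 head and 1 heart per sex). The germ plasm gene nanos1 stood at 15.0 and 259 TPM in female head and heart and at 0 in both males. The meiotic kinase gene wee2 stood at 16.5 and 481 TPM in the females, against 0 and 0.13 in male head and heart. The intestinal epithelium, stomach and exocrine pancreas lists were higher in female than in male head and differed little between the hearts. This rests on 1 library per sex and tissue, and the difference between tissues was not tested. The chitinase gene chia, which is abundant in stomach, stood at 1543 TPM in female head and 1.33 in male head. The trypsinogen gene prss1 stood at 761 and 1.59 in the same libraries.

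edgeR called 312 of 19276 genes, 298 higher in female and 14 higher in male. DESeq2 called 523 (488 and 35), limma on log2(TPM + 1) called 0 with 1232 at an unadjusted p under 0.05, and a rule of 4-fold in both tissues without a test gave 576 (431 and 145). All 298 genes higher in female had the same direction in both tissues, as had 12 of the 14 higher in male. The fit favours genes on which head and heart agree, so this agreement is no separate support. Of the 298, 265 had at least 1 TPM in ovary and at least 4 times their intestine level. With all such genes left out, a choice made after seeing the data, 35 calls were left (27 and 8). Each sex effect within a tissue rests on 1 library per sex, and leaving out a library leaves no residual degree of freedom.

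Oocyte and proliferation genes led the female calls. They included the histone genes hist1h2aa and hist1h4a, the ring finger gene mkrn3, the helicase gene ddx25, the transcription factor genes e2f1 and hes7.1, and birc5.1, a survivin gene that acts in cell division. All 30 tested oocyte genes were higher in female, and 27 passed over all genes and 28 over the list alone. Of the cell cycle list, 13 of 29 passed over all genes and 22 over the list alone. The cyclin B gene ccnb1 stood at 71.1 and 0.21 TPM in female and male head and at 2810 and 3.19 in female and male heart. Camera called both lists (adjusted p = 3.89e-62 and 4.13e-40), and neither with an estimated correlation (adjusted p = 0.862 for both). Of 21 meiosis and piRNA genes 3 were higher and 1 lower in female, or 6 and 1 when adjusted over the list alone (camera adjusted p = 5.18e-06, or adjusted p = 0.862 with an estimated correlation). The germ cell genes dazl and ddx4 were among the higher ones.

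Only 14 genes were called higher in male, and 3 of them carry a symbol. The dehydrogenase-like gene sccpdh.2 stood at 22.2 TPM in male head and 41.4 in male heart against 0.24 and 0 in the females (log2 fold change -8.61, SE 1.51, adjusted p = 3.74e-06, edgeR), and at 92.7 in testes. The meiotic gene tex11 reached 114 TPM in male heart against 0.34 in female heart, and 48.5 in testes. The V(D)J recombinase gene rag1 stood at 16.2 TPM in male head and 0.10 in female head, and at 0 in both hearts. DESeq2 did not call rag1 or nanos1.

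Camera called other lists with few or no single calls. All 26 immune genes and all 19 endothelium genes had negative fold changes for female against male, with median log2 of -1.58 and -1.71 (camera adjusted p = 1.36e-05 and 4.39e-05). The leukocyte gene lcp1 stood at 64.2 and 146 TPM in female and male head and at 2.24 and 10.7 in the hearts. Cardiac muscle (median -1.04, adjusted p = 8.99e-05), mitochondrial oxidation (-0.57, 1.85e-04) and lung epithelium (-1.19, 0.0277) were lower in female, and intestinal epithelium (1.79e-04), exocrine pancreas (1.85e-04) and stomach (0.0236) were higher by camera. Over the list alone, 2 members each of the intestinal and pancreas lists passed. Most of these shifts lay in 1 tissue. Female minus male mean log2(TPM + 1) was -0.12 in head and -1.47 in heart for the cardiac list, -0.13 and -0.98 for mitochondrial oxidation, 0.13 and -1.06 for lung epithelium and -0.27 and -1.84 for endothelium, where the oocyte list was 6.66 higher in female heart. For the intestinal, pancreas and stomach lists it was 1.85, 3.03 and 2.68 in head and 0.01, -0.06 and -0.01 in heart. The immune list was lower in both, at -0.86 and -0.76. The adjusted p was 0.862 for all 8 of these lists with an estimated correlation, and fry called 0 lists. The other 16 lists were not called by camera. Among these, the median, the mean and camera's direction differed in sign for glia, epidermis, and cartilage and bone.

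**Figure D2:**
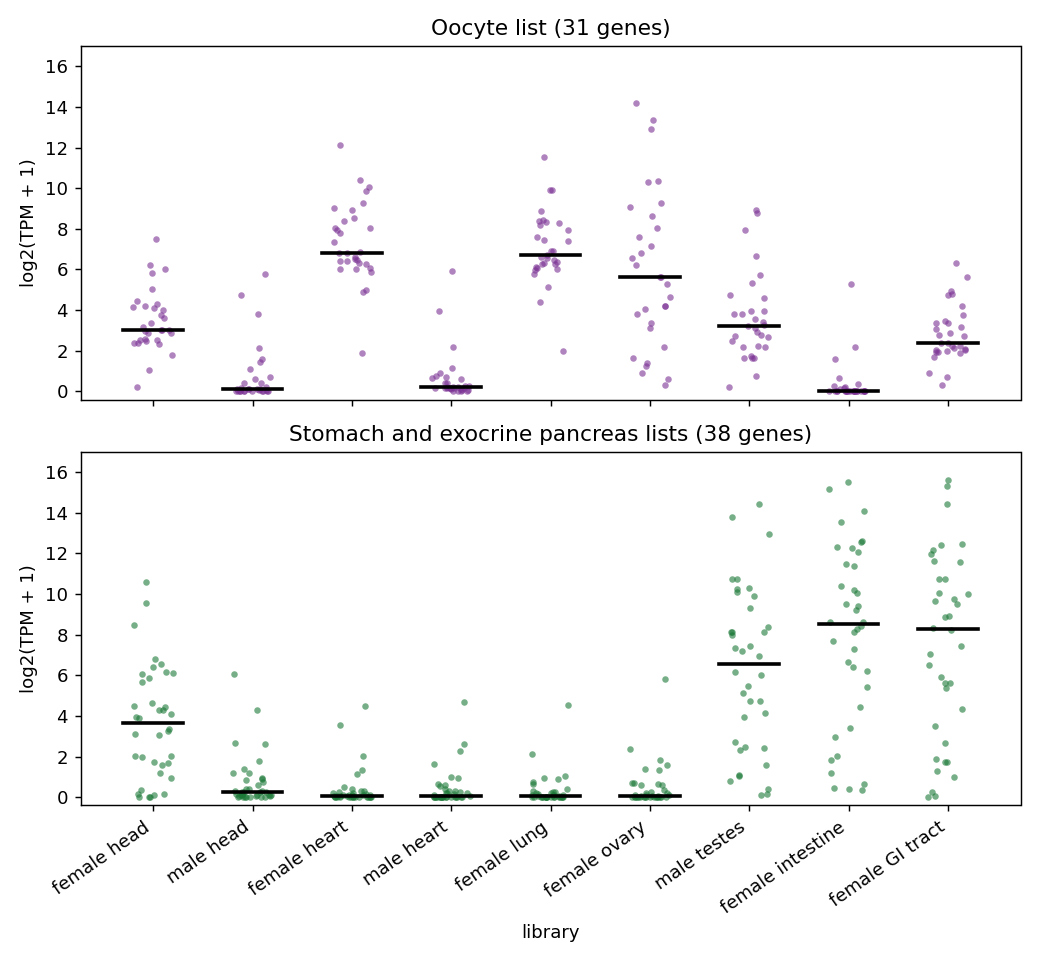
Levels, as log2(TPM + 1), of the 31 genes of the oocyte list (top) and the 38 genes of the stomach and exocrine pancreas lists (bottom) in each of the 9 libraries; each point is a gene and each bar the median over the list. The oocyte median was 6.83 in female heart, 6.70 in female lung and 5.63 in ovary, and the digestive median was 8.52 in intestine, 8.30 in GI tract, 6.55 in testes and 3.64 in female head.

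Ovary and testes were compared to describe the gonads. Ovary RNA was rich in maternal transcripts. The translational regulator gene btg4 reached 18969 TPM against 52.6 in testes, the oocyte translation factor gene eif4e1b 10607 against 14.8, the claudin gene cldn6.1 23187 against 57.8 and the egg coat gene zp4.2 1249 against 5.5. Testes RNA was rich in meiotic and ciliary transcripts, as well as digestive ones. The meiotic chromosome gene hormad1 stood at 473 TPM against 0 in ovary, the axonemal gene ccdc40 at 461 against 2.69, the sperm tail gene odf3 at 224 against 0.06, the testis-determining factor gene dmrt1 at 116 against 0.07 and the androgen synthesis gene cyp17a1 at 491 against 0.98.

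edgeR called 0 of 23090 genes between ovary and testes, with 6954 at an unadjusted p under 0.05 and a lowest adjusted p of 0.118. DESeq2 called 5714 (1987 higher in ovary, 3727 in testes) and limma on log2(TPM + 1) called 5240 (445 and 4795). The spread came from the head and heart pairs: edgeR called 11227 genes without the female heart and 10750 without the male heart. A rule of 4-fold and 10 TPM, with no test, gave 1351 genes higher in ovary and 5695 higher in testes. The median log2 fold change was -2.08 with TMM and -1.86 with DESeq2's size factors. For genes above 10 TPM the median TMM fold change lay 1.95 log2 above the TPM ratio. The direction of differences of about that size, and of some larger ones, therefore depends on the scale. Signs were opposite on the 2 scales for 4 of 31 oocyte, 6 of 29 cell cycle and 7 of 38 mitochondrial oxidation genes.

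By the size rule, the genes with the largest ratios towards ovary, beyond those above, were hist1h2am, hist1h2aa, nkap, rnf138, foxr1, prkrip1, tbpl2 and birc5.1. The oocyte-specific TATA-binding protein gene tbpl2 stood at 1075 TPM in ovary and 6.64 in testes, and nkap at 6239 and 34.9. Towards testes they were rflcii (7159 TPM against 0.06), rtbdn (2225 against 0), actb-like.1 (1566 against 0) and the smooth muscle actin gene acta2 (8344 against 5.82), together with digestive enzyme and transporter genes. Of these, chia stood at 22314 TPM in testes, prss1 at 13957, the chymotrypsin gene ctrc at 7862 and the peptide transporter gene slc15a1 at 5646. The same 4 genes stood between 1.56 and 4.17 TPM in ovary. Also among the largest ratios were ela3b, cela3a, ctrb2 and pgc-like.1.

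Of the oocyte list, 22 of 31 members were higher in ovary by TPM, and 26 by the edgeR fold change. The median TPM ratio was 2.61 log2, above 100% of 10000 random lists matched on expression. The list had an estimated inter-gene correlation of 0.974, which the random lists lack, so this percentile is not a test. Camera called the list higher in ovary (adjusted p = 0.00293) and the cell cycle list as well (0.0113; 16 of 29 members higher by TPM and 22 by edgeR, percentile 96.6). Lower in ovary by camera were the lists of meiosis and piRNA (median log2 TPM ratio -5.19, percentile 0, adjusted p = 0.00342), motile cilia (-4.47, 0, 0.00743), intestinal epithelium (-5.19, 0, 0.00724), stomach (-7.25, 0, 0.0233), liver (-2.15, 0.06, 0.00209), smooth muscle (-3.67, 0.03, 0.0113), neuron (-1.67, 0.76, 0.0162) and endothelium (-1.88, 1.59, 0.0491). With an estimated correlation the adjusted p was 0.801 for each of these 10 lists, and fry called 0. For mitochondrial oxidation and glycolysis, camera's direction was up while the median and mean fold changes were negative, and neither was called.

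The gonadal soma and sex steroid list was not called by camera (adjusted p = 0.273), had 6 of 25 members higher in ovary by TPM, and its median ratio of -1.55 lay at percentile 24.25. Adjusted over the list alone, edgeR called 12 meiosis and piRNA genes, 16 motile cilia genes, 5 spermatid and sperm genes and 7 gonadal soma and sex steroid genes lower in ovary. The meiotic cohesin gene rec8 (154 TPM in testes, 0.07 in ovary), the cilia gene cfap45 (359 and 0.27), the sperm tail gene odf2 (186 and 0.03), the inhibin gene inha (291 and 0) and the steroid transport gene star (94.7 and 0) were among them. The germ cell genes dazl (856 and 70.9) and ddx4 (664 and 80.1) did not pass, nor did the synaptonemal gene sycp1 (388 and 35.6), whose edgeR fold change of 0.72 had the opposite sign to its TPM ratio. Lower counts over the list alone were 9 of 29 for neuron, 3 of 13 for glia, 8 of 22 for cartilage and bone, 6 of 12 for smooth muscle, 7 of 26 for immune cells and 2 of 17 for glycolysis. The other 17 lists had 0 calls over the list alone.

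Intestine and GI tract, both female, were compared as overlapping parts of the gut. The serine protease gene prss3 stood at 4243 TPM in intestine against 48.2 in GI tract, the collagenase gene mmp13l at 332 against 4.06, and the bile acid feedback hormone gene fgf19 at 42.7 against 4.40. Several liver genes were higher in GI tract. The yolk precursor gene vtga2 stood at 375 TPM there and 0 in intestine, the retinol carrier gene rbp4 at 76.6 and 0, the protease inhibitor gene serpina1 at 44.5 and 0. The fatty acid binding gene fabp1, from the intestinal epithelium list, which was not called (camera adjusted p = 0.234, or adjusted p = 0.961 with an estimated correlation), stood at 1019 and 47.8. The most abundant digestive genes were close, with prss1 at 46124 and 40857 TPM and chia at 36882 and 50276.

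edgeR called 0 of 23090 genes between intestine and GI tract, with 231 at an unadjusted p under 0.05. DESeq2 called 31 (1 higher in intestine, 30 in GI tract), limma on log2(TPM + 1) called 0 with 725 at an unadjusted p under 0.05, and the rule of 4-fold and 10 TPM gave 115 genes higher in intestine and 229 in GI tract. Beyond those above, the size rule named ctrb1, mmp9, dnase1, alkbh4, pfkfb3, muc6, pglyrp1, inf2 and zbtb16 in intestine. In GI tract it named serpina3k, serpina3m, dhdh, the surfactant gene sftpc (67.3 TPM against 0) and the oocyte and cell cycle genes ccna1, ccnb1, cldn6.1, mkrn3 and hist1h2am. The meiotic cyclin gene ccna1 stood at 93.8 TPM in GI tract, 0.26 in intestine and 5094 in female heart.

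The liver list was the clearest difference between the gut libraries. Of its 25 members, 23 were higher in GI tract, with a median log2 TPM ratio of -2.15 for intestine over GI tract, and 8 passed in edgeR when adjusted over the list alone (camera adjusted p = 1.39e-24, or adjusted p = 0.591 with an estimated correlation). All 31 oocyte genes (median -2.33, camera adjusted p = 6.64e-06) and all 29 cell cycle genes (-1.50, 0.0101) were higher in GI tract. Erythrocyte genes (-1.30, 0.0279) were higher there too. Exocrine pancreas (0.55, 0.0198) and immune genes (0.52, 0.0101) were higher in intestine. The lung epithelium list was called lower in intestine (0.0198), with a median fold change of -0.07, a mean of -2.68 and a median TPM ratio of 0.06. Its surfactant genes sftpc and sftpb (26.7 TPM in GI tract, 0.07 in intestine) were the members with large differences. With an estimated correlation the adjusted p was 0.961 for these 6 lists, and fry called 0. The median ratios of the liver, oocyte, cell cycle and erythrocyte lists lay at percentile 0 of 10000 random lists, as did that of the intestinal epithelium list (-0.63, 24 of 32 members higher in GI tract), and those of exocrine pancreas and immune cells at 100. For the stomach, sperm, stress and glycolysis lists, none of them called, camera's direction was opposite to the sign of the median and the mean.

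Each tissue was then set against the mean of the other 6. Head and ovary gave calls. Ovary is 1 library. Over genes high in female heart and lung, its ratio to lung fell with relative transcript length, read from counts divided by TPM. The median log2 ratio of ovary over lung was 0.147 in the shortest group of these genes and -2.692 in the longest. The effect of this tilt on the ovary calls and the ovary-enriched genes was not tested. In head edgeR called 2300 genes, 2295 higher and 5 lower, and the most abundant called and enriched genes were the glycolytic aldolase gene aldoa (7433 and 6926 TPM), ybx3, krt5.4, tnnc2 and the fast troponin T gene tnnt3. In ovary it called 2903, 1885 higher and 1018 lower, led by the actin-binding profilin gene pfn1 (11064 TPM), eif4e1b, the small nucleolar ribonucleoprotein gene nop58 (6854), nkap and tmsb15b. The calls depended on the libraries behind the spread: without the female heart, head gave 8508 and ovary 12680, and without the male heart 9989 and 11969. The balance of directions moved as well. Head had 6456 higher and 2052 lower genes without the female heart, 6979 and 3010 without the male heart, and 3403 and 863 with limma on log2(TPM + 1). Ovary had more lower than higher genes in these settings, with 5068 and 7612 without the female heart, 4874 and 7095 without the male heart, and 896 higher and 3255 lower with limma. Head gave 1391 without the female head and 1315 without the male head.

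Heart, lung, testes, intestine and GI tract had 0 genes called by edgeR, with 3267, 1513, 4160, 3293 and 3162 at an unadjusted p under 0.05. DESeq2 called 2220, 419, 952, 1272 and 927 in that order, and limma on log2(TPM + 1) called 0, 0, 2498, 4 and 0. Without the female heart edgeR called 4438, 1724, 4374, 3105 and 2362. Leaving out the male heart gave 2921 in heart, 0 in lung, 3412 in testes, 3984 in intestine and 3007 in GI tract. Leaving out the female head gave 653 in heart, 136 in lung, 1024 in testes, 629 in intestine and 740 in GI tract, and leaving out the male head gave 553, 41, 920, 676 and 711.

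Camera called 14 lists in head, 13 in heart, 17 in lung, 12 in ovary, 12 in testes, 15 in intestine and 14 in GI tract, and 0 in each with an estimated correlation. Fry called 9 lists in head, 7 in heart, 9 in ovary and 0 in each of the others. In head, 27 of 29 skeletal muscle, 23 of 29 neuron, 24 of 27 photoreceptor and retina and 19 of 22 cartilage and bone genes were called higher over all genes. In heart, 29 of 34 cardiac and 28 of 38 mitochondrial oxidation genes passed when adjusted over the list alone (camera adjusted p = 1.04e-23 and 8.9e-22, or adjusted p = 0.552 with an estimated correlation). In lung, 15 of 19 endothelium, 12 of 15 erythrocyte and 6 of 15 lung epithelium genes passed over the list alone (camera 3.33e-07, 6.14e-06 and 0.012, or adjusted p = 0.564, 0.564 and 0.618 with an estimated correlation). Camera also called the oocyte and cell cycle lists higher in lung, with 31 of 31 and 29 of 29 members positive and 0 passing over the list alone (5.79e-04 and 0.00366, or adjusted p = 0.675 and 0.678 with an estimated correlation). In testes, 26 of 29 meiosis and piRNA, 22 of 24 motile cilia and 10 of 17 spermatid and sperm genes passed over the list alone (camera 1.04e-12, 6.49e-09 and 2.68e-04, or adjusted p = 0.561 with an estimated correlation). Digestive lists were called higher in testes too, with 19 of 32 intestinal epithelium, 10 of 13 stomach, 15 of 25 liver and 0 of 23 exocrine pancreas genes passing over the list alone (camera 8.12e-04, 0.00859, 3.27e-04 and 0.0304, or adjusted p = 0.862, 0.862, 0.561 and 0.862 with an estimated correlation). The cardiac list was called lower in testes (0.0142, or adjusted p = 0.862 with an estimated correlation) with a median of 0.06 and a mean of -0.22. In intestine and GI tract, 22 and 21 of 23 exocrine pancreas genes and 27 and 28 of 32 intestinal epithelium genes passed over the list alone.

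Tissue-enriched genes, counted by size alone, numbered 843 in head, 150 in heart, 123 in lung, 722 in ovary, 831 in testes, 37 in intestine and 4 in GI tract. Intestine and GI tract were counted apart and correlated at 0.923, and a gene at similar levels in both cannot pass for either. Testes, with a median of 32.2% of the GI tract level over digestive genes, limits the gut counts as well. The 2 gut counts therefore do not give the number of genes specific to the gut. In heart the most abundant were myl3, myl7, the cardiac actin gene actc1 (4777 and 11189 TPM), the myosin heavy chain gene myh6 (4084 and 11851) and tnni3. In lung they were the globin gene hbg1 (32225 TPM, against 14977 in female head and 996 in male head, so that it passed against the head mean and not against the female head), the surfactant genes sftpc (15017) and sftpb (6437), the pericyte signalling gene rgs5 (9357) and the caveolin gene cav1 (1481). In testes they were rflcii, the linker histone gene h1fx (3857), rtbdn, actb-like.1 and faim2 (1137). In intestine they were prss3, the elastase genes cela1 (2651) and cela3b (724), the chemokine gene cxcl14 (1389) and mmp13l, and in GI tract fabp1 and the thyroid hormone carrier gene ttr (18.7). With CPM scaled by TMM in place of TPM, the counts were 1846 in ovary, 460 in testes, 53 in lung and 100 in GI tract. Without the female heart, female lung and male testes libraries, a choice made after seeing the data, ovary had 1711, heart 328 and GI tract 81.

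By list, 24 of 29 meiosis and piRNA genes and 11 of 24 motile cilia genes were enriched in testes, and 22 of 31 skeletal muscle, 17 of 30 neuron and 13 of 27 photoreceptor and retina genes in head. In heart 21 of 34 cardiac genes and in lung 8 of 19 endothelium and 4 of 16 lung epithelium genes were enriched. Of the 31 oocyte genes only 4 were enriched in ovary, while 19 had their highest tissue mean in lung and 10 in ovary. The heart mean pools a female library with a male one, where the mean log2(TPM + 1) of the list was 7.32 and 0.66, and the female heart alone was above lung (7.07). The egg coat gene zp2 stood at 78.9 TPM in lung, 64.7 in female heart and 49.1 in ovary.

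**Figure D3:**
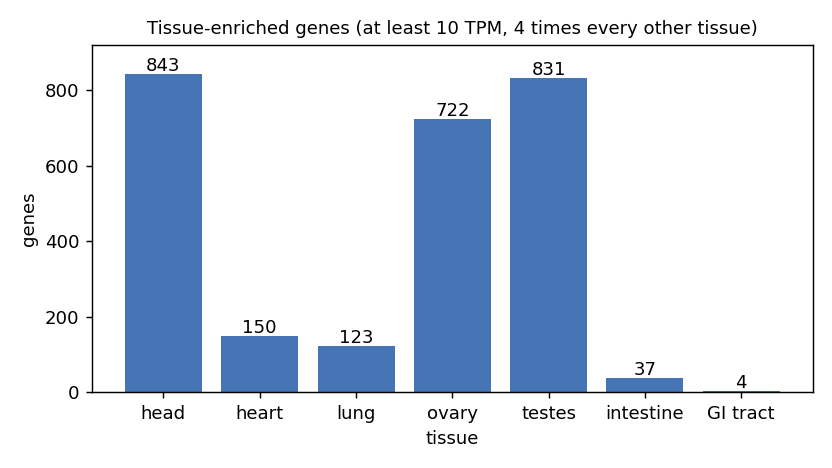
Number of tissue-enriched genes (y axis, from 0) in each of the 7 tissues (x axis), where a gene counts when it has at least 10 TPM in a tissue and at least 4 times the level of every other tissue. Head, testes and ovary had 843, 831 and 722 and GI tract 4. Intestine and GI tract are counted apart, so genes at similar levels in both cannot pass.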

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

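All tests of explanations in this part were chosen after the patterns had been seen. The test for GI tract material in the female head was tightened, and the test on female head and lung added and later required to hold on both sets of oocyte genes, after first outcomes were known.

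The erythrocyte list differed in direction between tissues. Its mean log2(TPM + 1) was 2.29 higher in female than in male head, while female minus male was -1.39 in heart. The globin gene hbg1 stood at 14977 TPM in female head and 996 in male head, against 6716 and 8216 in the hearts. Each side is 1 library, and the difference between tissues was not tested.

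The counts without a gene name, which enter no comparison, took up to 1.78% of a library (female heart, 95% Wilson interval 1.77 to 1.78), 1.68% in male heart and 0.0113% in ovary. This lies above the limit of 3 counts. No explanation was tested.

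Over 192 digestive genes with at least 50 TPM in GI tract and at least 50 times the level of both hearts, male head, lung and ovary, testes held a median of 32.2% of the GI tract level and female head 2.57%. The interquartile width of log2 testes over GI tract was 0.31, against 1.298 for testes over intestine, 1.35 for intestine over GI tract and 0.0295 in a simulated mixture. The observed width was 0.23 of that between the gut libraries, which argues against separate expression of these genes by testis cells, and GI tract material in the testes library may be a source. For female head, the width of 0.846 left that source open. The male's own gut also stays open: the yolk precursor gene vtga2 stood at the ratio of the other genes (log2 testes over GI tract -1.73, from 113 and 375 TPM, and 0 in intestine) but is a single gene, and the egg genes zp4 (22.9 and 26.7 TPM) and nanos1 (5.84 in each) stood in testes at the GI tract level, above that ratio.

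Genes of the oocyte list were at least as high, by their median, in female heart and lung as in ovary. Over 611 genes at least 20 times higher in ovary than in the male head and heart and intestine, female heart held a median of 12.95% of ovary, and the width of log2 heart over lung was 0.612, against 0.771 over 6968 other genes, a fraction of 0.794, so neither RNA of 1 source nor expression by heart and lung cells was excluded. The width of heart over ovary, 2.85, argues against carry-over from the ovary library. Over 534 genes at least 10 times higher in female heart and lung than in those 3 libraries, the width over lung was 0.678 for female head (1.434 over other genes) and 0.71 for GI tract (1.752), but over the 611 genes it was 2.038 and 1.92, wider than over other genes, so whether these libraries share oocyte RNA of 1 source stays open. The male testes library had a higher median over these genes (14.6 TPM) than female head (7.53) or GI tract (4.07), and neither its source nor differences between the female animals were tested.

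The ovary library did not match lung over the same 534 genes. The log2 ratio of ovary over lung was lower for longer transcripts (Spearman's rho across genes -0.36 over the 530 with a length). Its median was 0.15 in the shortest group and -2.69 in the longest. Length here is a relative value, read from counts divided by TPM in these same libraries and not from an annotation. The ratio of female heart over lung was also lower for longer transcripts (rho -0.165). Removing the length trend from ovary over lung left a width of 3.645, against 4.008 before, which argues against length as the whole cause. The stage of the oocytes in the sample was not tested and stays open.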

How the results depend on the processing

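Alternatives that left out genes by their ovary, lung or GI tract level, left out 3 libraries together, or put the block into DESeq2 or camera were chosen after seeing the data; the others were planned.

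The cause of the following changes was not tested. DESeq2 called 3907 genes between head and heart, 523 between female and male, 5714 between ovary and testes, 31 between intestine and GI tract and 17087 over the 7 tissues, where edgeR called 0, 312, 0, 0 and 5203. Limma on log2(TPM + 1) called 3912, 0, 5240, 0 and 10919. In head against heart edgeR called 1309 with a filter of 50 counts, 2784 with sex as a block and 2108 without genes high in ovary, and DESeq2 with the block called 3197. In female against male, edgeR called 35 without genes high in ovary and 32 without genes high in ovary or lung. Size rules without a test gave 576 genes for sex, 7046 for the gonads and 344 for the gut libraries. Over the 7 tissues edgeR called 2536 without a filter. Over fewer tissues it called 12839 with the gut as 1 tissue and 35079 without the female heart, female lung and male testes. The last setting leaves no lung or testes library, so neither total compares directly with those over the 7 tissues. Totals over tissues, here and below, add the calls of each tissue, so a gene can count more than once. Tissue-enriched genes numbered 1387 at 10 times and 5012 at 1 TPM, against 2710. With an estimated correlation 0 lists were called in head against heart, in sex, in the gonads and in the gut, and fry called 11, 0, 0 and 0. The estimated setting also rests on few residual degrees of freedom, so its losses do not measure correlation between members.

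Leaving out a head or heart library gave 458 to 10396 genes in head against heart, 0 to 11227 in ovary against testes, 0 in intestine against GI tract and 6475 to 37191 over the 7 tissues. The lowest and highest came without the male head and without the male heart in head against heart. In ovary against testes and over the 7 tissues the highest came without the female heart. In the head and heart fit the BCV was 0.448 without the female heart, against 0.761 with all 4 libraries. No BCV is given for the other left-out libraries or for the fits of all tissues. A lone library left in a tissue is assumed to vary like the others. Leave-one-out was not run for female against male, since no residual degree of freedom is left.

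The correlation of the head libraries was 0.952 as Pearson's r, 0.933 with 0.1 added to TPM and 0.953 over genes of at least 1 TPM in every library. With DESeq2's size factors in edgeR or without the 20 most abundant genes, each count of calls stayed within 1.5 times its value. Among named genes 0 reversed, but they had been picked for the largest folds in these data, which made a reversal unlikely. For sex 79 gene values kept their side of the threshold and 17 became weaker. For head against heart 96 kept it and 180 passed it. There no gene passed in the planned fit, so none could become weaker, and the fit with the block had chosen the genes.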

Other observations

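These ratios were computed after the digestive pattern had been seen. The reverse direction of the digestive pattern was examined over 84 genes with at least 50 TPM in testes. They were at least 50 times higher there than in intestine, both hearts, male head, lung and ovary. Over them GI tract held a median of 0.051% of the testes level. The choice required low levels in intestine, which correlated closely with GI tract, so a low GI tract level was favoured in advance. Over 8 genes at least 8 times higher in intestine than in GI tract, the median ratio of testes was 0.0405 to intestine and 0.479 to GI tract. The choice of genes fixed the gap between these 2 ratios, but testes levels took no part in it. Over the 192 digestive genes the median ratio of testes was 0.456 to intestine and 0.322 to GI tract. The 8 genes thus lay far below the first and near the second, as in a GI tract-like and not an intestine-like composition. This does not tell the GI tract sample from the male's own gut. For female head the ratio to GI tract was 0.0184. Over 10 genes at least 8 times higher in GI tract than in intestine, the ratio to GI tract was 0.3217 for testes and 0.0244 for female head. For testes the ratio of these 10 genes to intestine was 8.92.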
